A study of Mus musculus with 6 samples.

How the data were processed

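RNA was measured in donor-derived (CD45.2+) B cells that carried BCR-ABL1 and stained for B220 and BP-1, sorted from bone marrow at day 21 after transduction and transplantation, in 3 samples from Jup knockout and 3 from wild-type donors on the C57BL/6 background. Total RNA was amplified and its biotin-labelled cDNA hybridised to 1-colour Affymetrix whole-transcript arrays, per the labels' protocols. The deposited values are on the log2 scale, as their range shows, and were made with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. RMA in its usual form corrects the background, makes the intensity distributions of all arrays equal and summarises the probes of each probe set. It thereby removes any shift common to all genes of an array and compresses the changes of dim transcripts. Which options and which annotation were used in it is not given in the sources used here. The array medians were 7.53 to 7.61, so the rows used here did not have fully equal distributions.

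The value table held 35556 rows, each column of which belongs to 1 sample by its label. Gene symbols came from the platform annotation, which lists 23410 of these rows, 1621 of them with several symbols, and leaves 12146 rows unnamed here. Rows with exactly 1 symbol were tested, 21789 probe sets of 19939 genes. Symbols were compared with RefSeq of assembly GRCm38.p6 through their gene IDs; 0 needed an update and the IDs of 91 probe sets had no match. That assembly served only for names and for which genes neighbour Jup, since the build behind the array annotation is not named, and no coordinates are given. Depth in the sense of reads does not apply to arrays, and the number of arrays limits the precision.

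KO and WT were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior, prior degrees of freedom 4.33) on the deposited log2 values of all 6 arrays, with no covariate and no filter on dim probe sets. All differences are KO minus WT. P-values were adjusted by Benjamini-Hochberg over the 21789 probe sets, with a threshold of 0.05. Standard errors of single genes are the moderated ones. Those of granule gene means come from the unmoderated spread between arrays, and those marked as across genes from the spread between genes. A panel of 15 genes and 28 gene lists, 559 members of which 510 were measured, were fixed before the data were examined, as were the design and all alternatives but 1. The lists hold markers of myeloid, erythroid, T and NK, stromal and endothelial, megakaryocyte, plasma, mature B and stem cells, included to look for RNA of cells other than the sorted ones, and pathway genes. Each gene entered a list by its probe set with the highest mean over all arrays. The lists were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 28 lists. They were tested again with an estimated correlation per list and with fry, whose p asks whether the members move on balance one way without comparing them with other genes. Members were counted as adjusted over the list alone and over all probe sets. Of the list genes 45 have several probe sets, and for 3 of them these differ in sign.

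The genes named in the text follow a rule set before the data were examined. It takes Jup and the panel, then the 12 largest changes in each direction among probe sets past the threshold without overlap between KO and WT, filled up to 12 from the smallest unadjusted p where fewer passed, and then the 2 members with the highest and the 2 with the lowest moderated t of each list. Predicted genes and olfactory and vomeronasal receptors are counted but not named. From the list members, those that bear on the list's direction or that passed over the list alone are given. The sex-linked genes were also set before the data were examined. Other genes outside the rule are said to have been named after their values were seen.

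The fit was tested on simulated data with independent genes, 21789 probe sets and 200 changed ones, in 20 runs. It recovered 93.8% of the changes of log2 size 1 and 37.0% of those of size 0.5, and 5.3% of the calls were false. Camera called 1 of 540 unshifted lists and 20 of 20 lists shifted by 0.3. Real genes are correlated, so this says nothing of camera's error where genes move together. Nor do the recovered shares carry over to the data, since they depend on how many changes were planted and how variable those genes were. In the data Mt2, for example, missed the threshold at a log2 difference of -2.003 (limma adjusted p = 0.139). Alternatives were a filter on dim probe sets (mean below the 40th percentile), all rows of the table, 1 probe set per gene, a trended and robust prior, array weights, a further quantile normalization, centring on the array median, the replicate number as a block, each array left out, an adjusted p of 0.1, the mean of a gene's probe sets, and windows of 5 and 20 Mb around Jup. A removal of the trend with brightness was chosen after seeing the data.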

Results

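Gene expression was profiled on microarrays in leukaemic mouse B cells that carried or lacked gamma-catenin. Gamma-catenin, also called plakoglobin and encoded by Jup, is a component of desmosomes and adherens junctions and a close relative of beta-catenin. Chimeric mice were made with fetal liver cells of Jup knockout (KO) or wild-type (WT) embryos, and their bone marrow was transduced with a retrovirus carrying BCR-ABL1, the fusion kinase of Philadelphia chromosome-positive leukaemia, together with green fluorescent protein. Fluorescent B220+ BP-1+ B cells of the donor type were sorted from transplanted recipients at day 21. There were 3 KO and 3 WT samples, labelled as biological replicates, each on 1 array. Array medians lay between 7.53 and 7.61 on the log2 scale and any 2 arrays correlated at Pearson's r of 0.991 to 0.996 across probe sets, which are not independent replicates. The number of arrays limits the precision of every value.

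The comparison asked which transcripts differ between BCR-ABL1+ B cells with and without gamma-catenin, since the study's title ties Jup to the progression of this leukaemia. The targeted gene came first. Jup (probe set 10391103) measured 7.04, 7.06 and 7.27 in the KO arrays and 8.04, 7.62 and 8.51 in the WT arrays, so the groups did not overlap. The KO mean was 7.13 ± 0.13 (SD, n = 3) and the WT mean 8.06 ± 0.44 (SD, n = 3), a log2 difference of -0.93 (SE 0.20), or 1.91-fold lower. This did not pass over all probe sets (limma, adjusted p = 0.171), and it passed when adjusted over the fixed panel of genes alone (adjusted p = 0.00867). Which part of Jup the KO allele lacks, and whether the probe set lies in it, is not given in the sources used here, so the values check the labels only in part.

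Neutrophil granule genes led the transcripts that were higher without Jup. Mpo, the myeloperoxidase of primary granules, was 3.04-fold higher in KO, with a log2 difference of 1.60 (SE 0.12, limma adjusted p = 0.00512). Elane, neutrophil elastase, was 2.37-fold higher and Ctsg, cathepsin G of the same granules, 2.20-fold higher. Hspb8, a small heat shock protein, fell most among the named genes and was 4.14-fold lower in KO. In all, 11 probe sets rose and 15 fell among 21789 tested at limma adjusted p under 0.05, and the KO and WT arrays did not overlap in any of these 26.

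Other transcripts that rose were Slc30a4, a zinc transporter (2.33-fold), Pde9a, a cyclic GMP phosphodiesterase (1.89-fold), Esco1, an acetyltransferase of cohesin (1.78-fold), and Zbtb20, a zinc finger transcription factor (1.70-fold). Car1, a carbonic anhydrase of red cells, rose 1.67-fold, Zc3h12b 1.58-fold, the nuclear noncoding RNA Malat1 1.55-fold and the urea transporter Slc14a1 1.51-fold. Lgr5, a receptor for R-spondins and a known target of beta-catenin, had a larger log2 difference of 1.67 (SE 0.23) but missed the threshold (limma adjusted p = 0.0508). Without KO replicate 2, only 2 probe sets rose and 3 fell, and without KO replicate 3, 1 rose and 4 fell.

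Among the transcripts that fell, Crim1, a transmembrane protein that binds bone morphogenetic proteins, was 2.87-fold lower in KO. Hmgcll1, an enzyme related to the lyase of ketone body synthesis, was 2.43-fold lower and the cation channel gene Trpc4 2.38-fold lower. Foxc1, a forkhead transcription factor, was 2.23-fold lower and Rgs8, a regulator of G protein signalling, 2.22-fold lower, with the lowest adjusted p of all (log2 difference -1.15, SE 0.07, limma adjusted p = 0.00438). Rps6ka6, a kinase of the RSK family, fell 2.10-fold, the matrix protein gene Sparc 1.94-fold, Rnase9 1.93-fold and Eng, the co-receptor endoglin, 1.77-fold. In both groups Rps6ka6 (5.84 in KO, 6.92 in WT) and Rnase9 (6.36 and 7.31) lay below the array medians, as did Car1 among those that rose (7.39 and 6.65). Bnip3, which acts in the removal of mitochondria, fell on both of its probe sets, by 1.80-fold and 1.74-fold. Ldlrad4, Ly96 and Impact also fell, by 0.73, 0.65 and 0.60 on the log2 scale, and are named after their values were seen.

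**Figure D1:**
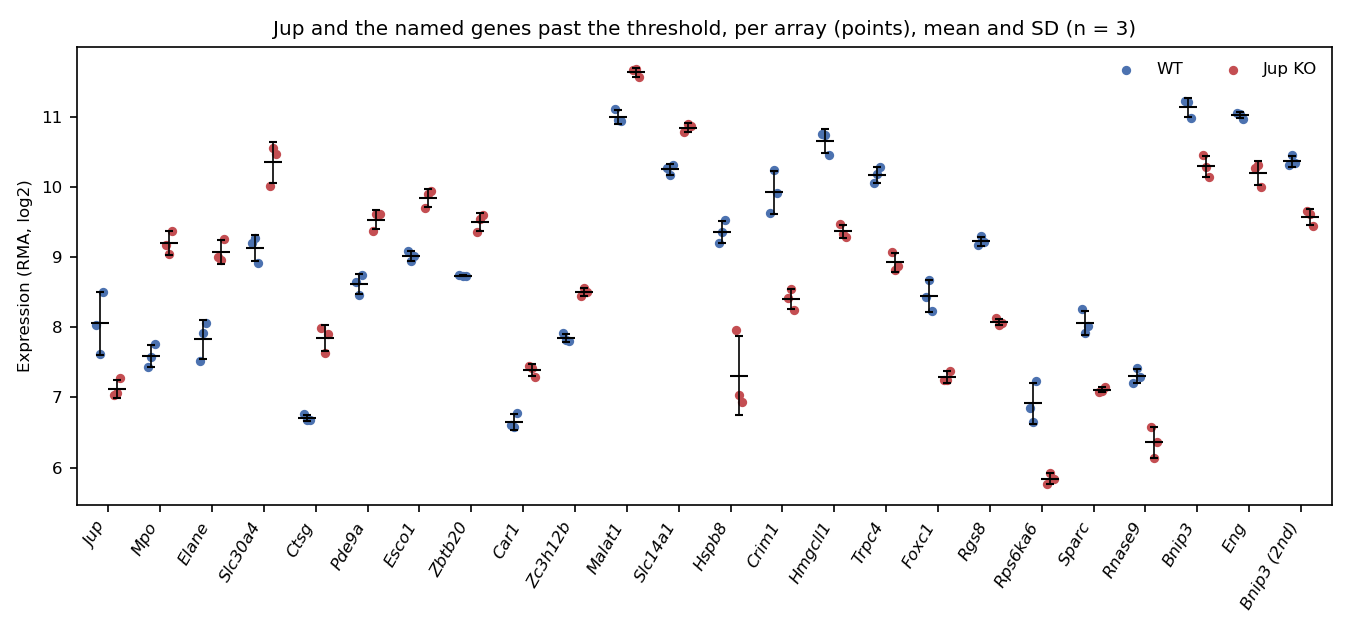
Deposited log2 expression of Jup and of the named genes past the threshold (x axis) in each array (points; blue WT, red Jup KO), with the mean (wide tick) and SD (bars) of 3 arrays per group; the y axis is log2 RMA expression. The KO and WT arrays did not overlap for Jup, the other genes were chosen for having no overlap, and Hspb8 had the largest SD in KO (0.56).

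The count changed with the arrays used, and leaving out an array also lowers the number of samples. Only Rgs8, Mpo, Trpc4 and Hmgcll1 passed with each of the 6 arrays left out in turn, whereas all 26 probe sets kept their sign. Leaving out KO replicate 1 gave 41 up and 41 down, WT replicate 1 gave 3 and 5, WT replicate 2 gave 8 and 13, and WT replicate 3 gave 1 and 7. At an unadjusted p under 0.05, 977 probe sets were higher and 1031 lower, against 1089 expected by chance in both directions together. The KO and WT arrays did not overlap for 14% of the probe sets, where chance gives 10%.

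The arrays also differed in donor sex as read from sex-linked transcripts. Xist, the RNA of the inactive X chromosome, was between 13.03 and 13.38 in 5 arrays and 6.20 in WT replicate 2, where the Y-linked genes Kdm5d, Eif2s3y and Uty were at 8.57, 8.90 and 10.09. In the other arrays these Y-linked genes lay between 3.52 and 5.54. No KO array was of that kind, so sex was uneven between the genotypes.

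Of the 15 genes of the fixed panel, 13 were measured by a probe set with 1 gene symbol. Adjusted over the list alone, 2 rose and 3 fell, and over all probe sets 0 did, in limma. Ccnd2, which encodes cyclin D2, was 0.85 higher (SE 0.21) and the adhesion receptor Cd44 1.02 higher (SE 0.26) on the log2 scale in KO. Bcl2, which blocks apoptosis, and the growth regulator Myc were lower by log2 differences of -0.49 (SE 0.09) and -0.48 (SE 0.14), and Jup was the other. At an unadjusted p under 0.05, 2 were higher and 4 lower, the further one being Enpep, which encodes BP-1. The transcripts of the sort gate gave -0.23 for Enpep and 0.19 for Ptprc (B220 and CD45). Ctnnb1, which encodes beta-catenin, gave -0.04, its partner Lef1 -0.01 and Abl1 -0.01, all near 0, and Pim1 gave -0.13, Mcl1 0.17 and Bcl2l1 0.06. The signs of Ctnnb1, Lef1, Abl1 and Bcl2l1 turned under some other scaling, weighting or choice of arrays, and Mcl1 was at 0.278 without WT replicate 1 and 0.102 without WT replicate 3.

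The 28 gene lists were tested against all other genes with camera at a preset correlation of 0.01 between genes. With that test 12 lists passed, 6 toward higher and 6 toward lower expression in KO. With a correlation estimated per list, 0 passed after adjustment and 2 had an unadjusted p under 0.05, those of the myeloid and mature B cell lists. With fry, 0 passed after adjustment.

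Myeloid cell markers were the list with the lowest p. Of 22 measured members 19 were higher in KO, with a median log2 difference of 0.61, and 15 rose adjusted over the list alone, with 3 over all probe sets (Mpo, Elane and Ctsg). The camera adjusted p was 2.01e-20, against an adjusted p of 0.646 with an estimated correlation. Csf1r and Cd14, markers of monocytes and macrophages, gave log2 differences of -0.11 and -0.15 and did not pass. Both were dim, Csf1r at 6.53 in KO and 6.65 in WT and Cd14 at 5.90 and 6.06, and RMA compresses changes of dim transcripts. Single arrays moved both: Csf1r was at -0.060 without KO replicate 2 and -0.177 without KO replicate 3, and Cd14 at -0.084 without KO replicate 2, -0.263 without WT replicate 1 and -0.013 without WT replicate 2. The late neutrophil genes were uneven within WT, where the mean of 8 of them was 8.07, 8.79 and 8.22 in replicates 1, 2 and 3, against 8.99 to 9.07 in KO. The mean of the 4 primary granule genes on the list was 7.10, 7.34 and 7.39 in WT and 8.34 to 8.65 in KO.

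**Figure D2:**
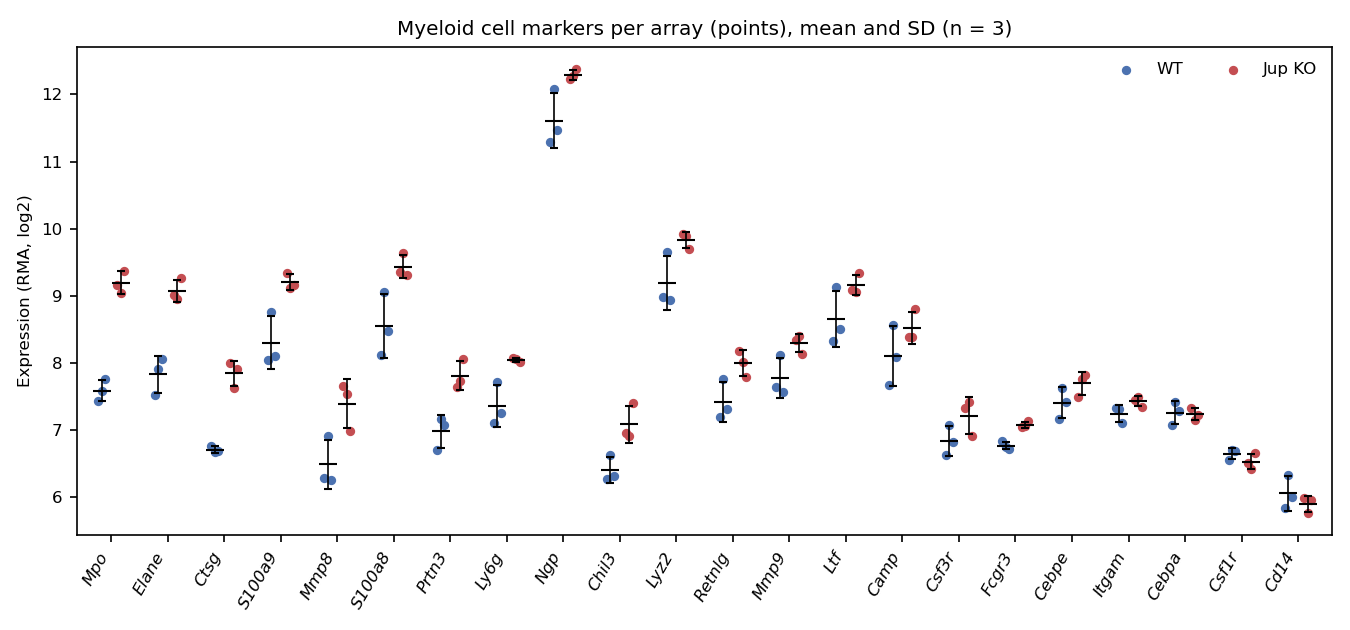
Deposited log2 expression (y axis) of the 22 measured myeloid cell markers (x axis, ordered by log2 difference) in each array (points; blue WT, red Jup KO), with the mean (wide tick) and SD (bars) of 3 arrays per group. Of the 22 genes 19 had a higher mean in KO, and Mpo had the largest log2 difference (1.60).

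Genes of mature B cells and antigen presentation were also higher in KO. As the mean deviation of the members from their WT means, the KO arrays were at 0.280, 0.485 and 0.396 and the highest WT array at 0.198, and the myeloid markers were higher in the same 3 arrays. Of 20 measured members 19 were higher, with a median log2 difference of 0.28, and 7 rose adjusted over the list alone, with 0 over all probe sets. Cd22, an inhibitory co-receptor of the B cell receptor, gave 1.28 (SE 0.22) and Ms4a1, which encodes CD20, 1.29 (SE 0.28). The list's lowest members by moderated t were Bank1 at -0.10 (SE 0.15) and the antigen presentation gene H2-Ab1 at 0.02 (SE 0.10). The camera adjusted p was 4.76e-09, and the adjusted p was 0.646 with an estimated correlation. The FOXO target list had a median of 0.19 (camera adjusted p = 1.93e-05, adjusted p = 0.701 with an estimated correlation), and 6 of its 20 members rose adjusted over the list alone, among them Klf2, a transcription factor of lymphocyte quiescence (0.81, SE 0.19), and Rag2, a subunit of the V(D)J recombinase (0.42, SE 0.10). Early B-lineage genes had a median of only 0.06 (camera adjusted p = 0.00126, adjusted p = 0.701 with an estimated correlation), and 2 of 21, Rag2 and the transcription factor gene Bach2 (1.02, SE 0.23), rose adjusted over the list alone. Homing and adhesion receptors had a median of 0.09 (camera adjusted p = 0.00747, adjusted p = 0.701 with an estimated correlation), and 2 of 15, Cd44 and the chemokine receptor gene Ccr7 (0.42, SE 0.10), rose adjusted over the list alone. Over all probe sets 0 members of these 3 lists passed in limma, while at an unadjusted p under 0.05 9 FOXO targets, 5 early B-lineage genes and 5 homing receptors were higher and 1, 0 and 1 lower. For the mature B cell genes these counts were 8 higher and 0 lower. By the mean deviation of their members, FOXO targets were lower in KO replicate 1 (0.107) than in WT replicate 1 (0.158), and so were early B-lineage genes (0.046 against 0.052).

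Growth and energy genes had slightly lower means in KO, a difference carried mostly by KO replicates 2 and 3. All 27 measured MYC targets and ribosome biogenesis genes had a lower KO mean, with a median of -0.17 (camera adjusted p = 5.26e-07, adjusted p = 0.701 with an estimated correlation). No member passed, adjusted over the list alone or over all probe sets; the lowest were Dctpp1 (-0.44, SE 0.11) and Mrto4 (-0.27, SE 0.09). Of 28 oxidative phosphorylation genes 26 were lower, with a median of -0.13 (camera adjusted p = 3.90e-06, adjusted p = 0.701 with an estimated correlation), led by the complex I genes Ndufb8 and Ndufa8 (both -0.27). Glycolysis genes had a median of -0.12 (camera adjusted p = 0.00291, adjusted p = 0.701 with an estimated correlation), with Aldoa at -0.33 and Tpi1 at -0.22. Ribosomal protein genes had a median of -0.07 (camera adjusted p = 0.00325, adjusted p = 0.701 with an estimated correlation), with Rpl13 at -0.21 and Rps3 at -0.20. In these last 3 lists 0 members passed in limma, adjusted over the list alone or over all probe sets. At an unadjusted p under 0.05, 4 MYC targets, 6 oxidative phosphorylation, 3 glycolysis and 3 ribosomal protein genes were lower and 0 were higher. Glycolysis and ribosomal proteins lost their call without KO replicate 2 (adjusted p = 0.0557 and 0.0527) and without WT replicate 1 (0.0699 and 0.121). KO replicate 1 lay nearer to the WT level than the other KO arrays: 15 of its 27 MYC list members were above the WT mean, against 0 in KO replicate 2 and 2 in KO replicate 3. As the mean deviation of a list's members from their WT means, the MYC list was at -0.013, -0.301 and -0.217 in KO replicates 1, 2 and 3, oxidative phosphorylation at -0.041, -0.175 and -0.173, glycolysis at 0.021, -0.209 and -0.186, and ribosomal proteins at -0.035, -0.125 and -0.092. Without KO replicate 1 the camera adjusted p of the MYC list was 5.71e-13, and without KO replicate 2 it was 0.00121. The myeloid markers, by the same measure, were at 0.603, 0.569 and 0.612, alike in the 3 KO arrays.

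Interferon response genes were lower in KO, 19 of 24 measured, with a median of -0.29 (camera adjusted p = 7.89e-05, adjusted p = 0.732 with an estimated correlation). The p53 target list had a median of -0.21, with 13 of 16 lower (camera adjusted p = 0.00199, adjusted p = 0.701 with an estimated correlation). In both lists 0 members passed in limma, adjusted over the list alone or over all probe sets, and 6 of each were lower at an unadjusted p under 0.05. Both calls rested on WT replicate 1, without which the camera adjusted p was 0.432 and 0.408. By the mean deviation of their members, WT replicate 3 (-0.389 for interferon and -0.174 for p53) lay among the KO arrays (-0.466 to -0.189 and -0.333 to -0.046), while WT replicate 1 was at 0.383 and 0.189. Among the interferon genes Usp18 gave -0.68 (SE 0.20) and Rtp4 -0.75 (SE 0.24), and among the p53 targets Polk gave -0.39 (SE 0.10) and the death receptor gene Tnfrsf10b -0.71 (SE 0.21). Immediate-early and heat shock genes had a median of 0.07 at the edge of the threshold (camera adjusted p = 0.0483, adjusted p = 0.732 with an estimated correlation). Egr1 (0.42, SE 0.10) was the 1 of their 17 members that rose adjusted over the list alone, with 0 over all probe sets, and Klf6 gave 0.34 (SE 0.11). The list's mean deviation was 0.312 in KO replicate 1 and 0.021 and 0.007 in the other KO arrays, and WT replicate 1 was at 0.144. The call was lost without KO replicate 1 (0.649), WT replicate 2 (0.256) or WT replicate 3 (0.179).

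The 16 other lists did not pass with camera. Among 17 TCF and catenin target genes (median 0.01, camera adjusted p = 0.301) members went both ways: adjusted over the list alone, Lgr5, Tnfrsf19 (0.88, SE 0.19), Cd44 and Axin2 (0.52, SE 0.16) rose and Myc fell, with 0 over all probe sets. Axin2, a feedback inhibitor of beta-catenin signalling, is named after its value was seen, and gave 0.316 without KO replicate 2. The catenins, cadherins and desmosomal genes other than Jup had a median of -0.05 (camera adjusted p = 0.387), with 0 members past either adjustment and 1 lower at an unadjusted p under 0.05. Of 11 STAT5 targets (camera adjusted p = 0.738) Ccnd2 rose and Cish (-0.52, SE 0.11) and Socs3 (-0.79, SE 0.17), both cytokine feedback inhibitors, fell adjusted over the list alone. Among RAS-ERK feedback genes (camera adjusted p = 0.411) Egr1 rose and the phosphatase gene Dusp5 (-0.48, SE 0.10) fell, in the BCL2 family (0.499) Bcl2 fell, and among NF-kB targets (0.863) Tnf (-1.24, SE 0.18) fell, each adjusted over the list alone. Over all probe sets 0 members of these lists passed.

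The marker lists of other cell types gave no camera call apart from the myeloid and mature B cell lists. Among erythroid markers (camera adjusted p = 0.581, with a median of -0.004 and a mean of 0.03) Car1 rose under both adjustments. Among stromal and endothelial markers (0.780) Sparc fell under both, and Igfbp4 (0.90, SE 0.24) rose adjusted over the list alone. Among stem and progenitor genes (0.931) Mycn (-0.75, SE 0.16) fell adjusted over the list alone. Plasma cell genes were just outside the threshold (median -0.14, camera adjusted p = 0.0577), and 8 of 10 were lower and 2 higher. The transcription factor gene Xbp1 was at -0.28 (SE 0.09) and Mzb1 at -0.32 (SE 0.12), or -0.200 without KO replicate 3. Megakaryocyte (0.738) and T and NK cell markers (0.780) had 0 members past either adjustment. The same held for G2/M and mitosis genes (0.366), DNA replication genes (0.373), cholesterol synthesis genes (0.437) and ATF4 and unfolded protein response genes (0.738). At an unadjusted p under 0.05 in limma, 0 megakaryocyte, G2/M and cholesterol genes passed, 1 T and NK marker was higher and 2 lower, 1 DNA replication gene was lower, and 2 ATF4 genes were higher and 2 lower. In 3 lists the signs differed: camera's direction was up for erythroid markers and for NF-kB targets (median 0.02, mean -0.07), and down for stem and progenitor genes (median 0.001, mean -0.009).

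**Figure D3:**
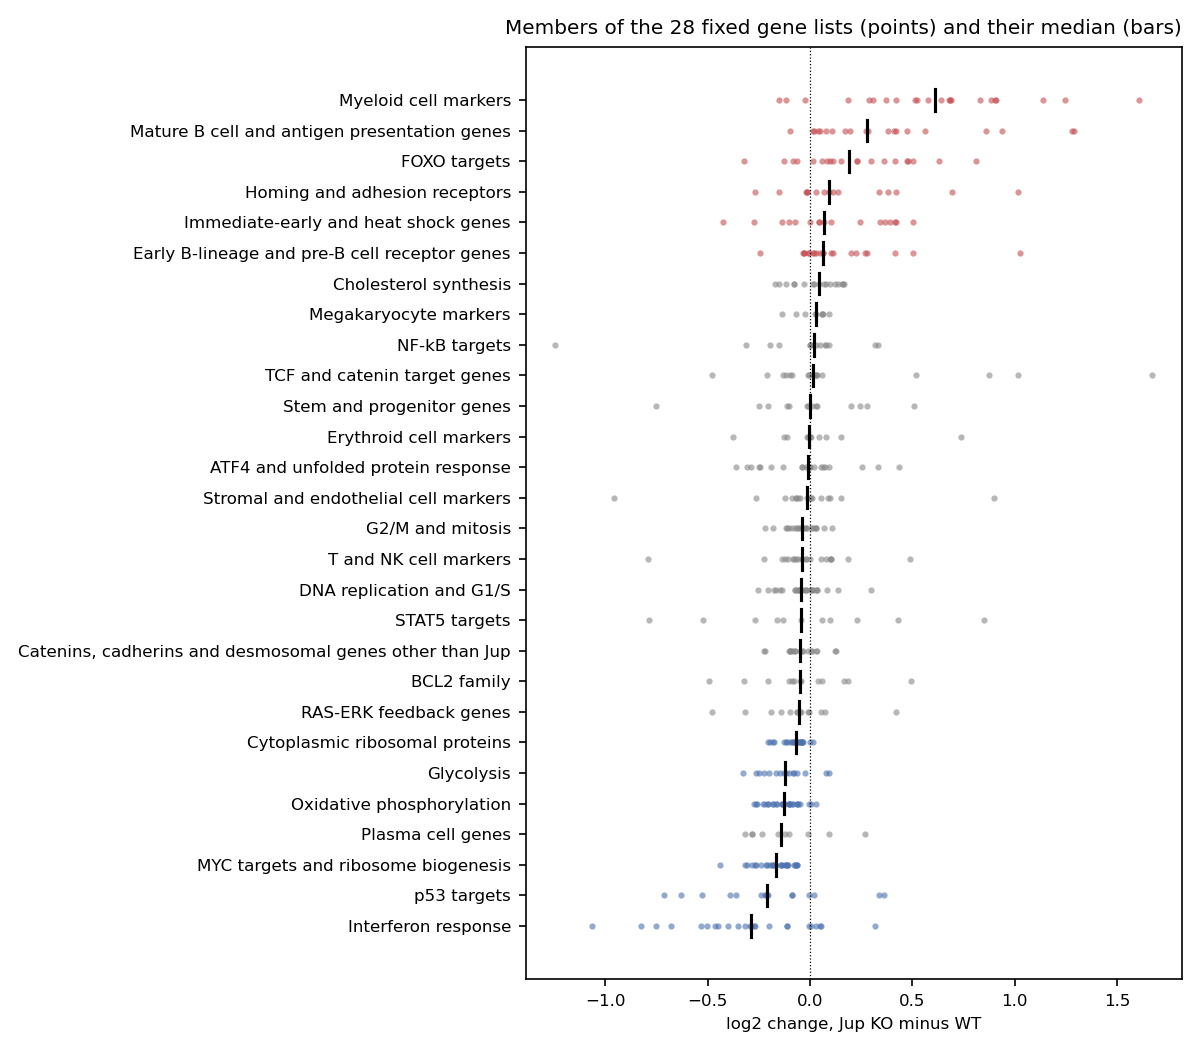
Log2 differences, Jup KO minus WT (x axis), of the measured members (points) of the 28 gene lists (y axis), with each list's median (black bar); red lists passed toward higher, blue toward lower expression in KO with camera at a preset correlation, and grey ones did not pass. Myeloid markers had the highest median (0.61) and interferon response genes the lowest (-0.29), and 0 lists passed with an estimated correlation.

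Genes within 10 Mb of Jup were not distinguished from other genes by camera. Their 380 members had a median log2 difference of -0.02, and camera gave p = 0.865 with its direction up, opposite to the median (0.883 with an estimated correlation). None passed singly within 10 Mb in limma over all probe sets, although 1, Mpo, did within 20 Mb, and within 10 Mb 23 were higher and 14 lower at an unadjusted p under 0.05.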

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

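The fit over all rows was set before the data were examined, and no other test was made here. Rows of the value table that name no gene stood outside the comparison, and 4 signals in them passed when all its rows were fitted together with limma. The largest absolute change on the array was in them: a block of 50 unnamed probe sets with identical values was at 7.05 ± 0.24 (SD, n = 3) in KO and 9.61 ± 0.38 (SD, n = 3) in WT, a log2 difference of -2.55 (SE 0.21, limma adjusted p = 0.00442). As these 50 rows share 1 measurement, they count once. The unnamed probe set 10340114 was higher in KO by 1.63 (SE 0.11, limma adjusted p = 0.00442), the unnamed probe set 10403013 by 1.27 (SE 0.12, limma adjusted p = 0.0128), and the unnamed probe set 10338630 by 0.74 (SE 0.09, limma adjusted p = 0.0402), the last with a mean of only 4.17 in KO and 3.42 in WT. What these probe sets measure was not worked out, and no explanation was tested.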

How the results depend on the processing

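The removal of the brightness trend was chosen after seeing the data, and the other alternatives before the data were examined. The cause of each change below was not tested, except that leaving out an array lowers the number of samples. Probe sets higher and lower in KO numbered 11 and 15 with all arrays, 11 and 13 without dim probe sets, 10 and 59 over all rows (50 of which share 1 measurement), 13 and 20 with 1 probe set per gene, 17 and 23 with a trended and robust prior, 93 and 57 with array weights, 7 and 10 after a further quantile normalization, 17 and 19 after centring, 25 and 33 at an adjusted p of 0.1, and 8 and 10 with the brightness trend removed. With an array left out they ranged from 1 to 41 and from 3 to 41. Shared with the 26 calls were 22, 5 and 4 without KO replicates 1, 2 and 3, and 6, 9 and 5 without WT replicates 1, 2 and 3, and all 26 kept their sign in each. Jup ranged from -1.147 to -0.703 with an array left out and passed in none of the settings over all probe sets (lowest adjusted p 0.0551, without WT replicate 2). The scalings moved the median of all probe sets by less than 0.1.

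KO and WT share replicate numbers, and whether these pair the samples was not settled. The deviations of same-numbered samples correlated at 0.104, -0.004 and 0.275 across probe sets. The samples numbered 3 correlated best with each other, but not every sample did so with its own number. With the replicate block 8 probe sets rose and 11 fell, 8 of them shared with the 26 calls, the plasma cell list passed (adjusted p = 0.0349), and the stem and progenitor list turned direction (0.853). The camera adjusted p with the block was 1.76e-06 for interferon response and 0.000653 for p53 targets, against 7.89e-05 and 0.00199 without it.

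Of the 28 lists, 12 passed, 9 to 13 with an array left out, 0 with an estimated correlation and 0 with fry. With an estimated correlation the adjusted p was 0.646 for myeloid and mature B cell genes, 0.732 for interferon response and immediate-early genes, and 0.701 for MYC targets, oxidative phosphorylation, FOXO targets, early B-lineage genes, p53 targets, glycolysis, ribosomal proteins and homing receptors. With fry it was 0.206 for myeloid genes, 0.282 for mature B cell genes, oxidative phosphorylation and ribosomal proteins, 0.325 for homing receptors, 0.370 for early B-lineage genes, 0.372 for MYC and FOXO targets, 0.384 for glycolysis, 0.385 for p53 targets, 0.654 for interferon response and 0.720 for immediate-early genes. The immediate-early list also missed the threshold without dim probe sets (0.0927), after quantile normalization (0.0862), after centring (0.0602) and with the brightness trend removed (0.110), as did ribosomal proteins with that trend removed (0.101). The plasma cell list passed with a trended and robust prior (0.0491) and the cholesterol list with array weights (0.0417).

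With an array left out, the adjusted p of the called lists that missed the threshold at least once ranged from 2.40e-06 to 0.408 for p53 targets and from 1.41e-15 to 0.432 for interferon response (both lost without WT replicate 1), from 0.00381 to 0.649 for immediate-early genes, from 4.96e-06 to 0.0699 for glycolysis and from 0.000854 to 0.121 for ribosomal proteins. Lists not called that passed or turned direction ranged from 0.0775 to 0.928 for TCF targets, 0.00377 to 0.949 for G2/M (passing without WT replicate 3), 0.00412 to 0.830 for DNA replication (passing without KO replicate 1), 0.133 to 0.875 for STAT5 targets, 0.00436 to 0.432 for plasma cells (passing without KO replicate 2, or WT replicate 3 at 0.00675), 0.649 to 0.794 for stem and progenitor genes, 0.145 to 0.853 for erythroid, 0.276 to 0.949 for T and NK, 0.0699 to 0.881 for stromal and 0.238 to 0.949 for megakaryocyte markers, 0.0153 to 0.937 for cholesterol synthesis (passing without KO replicate 2, or WT replicate 1 at 0.0456), 0.157 to 0.770 for ATF4, and 0.115 to 0.993 for NF-kB targets. Genes near Jup ranged from 0.612 to 0.980.

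Directions of lists that were not called also turned without dim probe sets (stem and progenitor genes 0.655, T and NK 0.308, NF-kB 0.951), with a trended prior (stem 0.910), with array weights (STAT5 0.872, erythroid 0.843, megakaryocyte 0.843, genes near Jup 0.903), after quantile normalization (stem 0.843), with the brightness trend removed (stem 0.869), with fry (NF-kB 0.870, genes near Jup 0.689) and within 20 Mb of Jup (0.871). Of the genes named in the text 78 probe sets were followed through the settings, and 74 of these kept their sign in every setting run. Ctnnb1 was at 0.000 with array weights, Lef1 at 0.008 and Abl1 at 0.015 after quantile normalization, and Lef1 at 0.023 and Abl1 at 0.025 with the brightness trend removed. With an array left out Abl1 ranged from -0.028 to 0.028 and Bcl2l1 from -0.075 to 0.188. Low signal over background limits the dim probe sets, whose changes RMA compresses.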

Other observations

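The tests of other splits, donor sex, granule genes, early myeloid genes, brightness and later-stage genes were chosen after the results were seen, as was that of further neutrophil genes, whose values had not been looked at when it was set, whereas the fits without an array and with an estimated correlation were set before the data were examined. Several groups of genes that were not fixed as lists stood out by their values, although Tnf is also on the NF-kB target list. Of these groups 3 are described and no test of them as groups is used, since genes picked for their values cannot test the pattern that picked them. Among the cytokine genes of the TNF family 10 of 15 measured ligands had a lower mean in KO, with a median log2 difference of -0.12. Tnf gave -1.24, Lta -0.92 and Tnfsf11, the ligand that drives osteoclast formation, -0.81. The metal-binding metallothioneins had 3 of 4 members lower, with Mt2 at -2.003 and Mt1 at -1.04, while Mt3 (-0.038) and Mt4 (0.037) were near 0. The immunoglobulin kappa variable genes, which are used once light chains are rearranged, had a higher mean in KO in 8 of 8 measured cases, with a median of 0.67, and resemble each other, so that probe sets can read more than 1 of them. No member of the 3 groups passed singly in limma over all probe sets.

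The number of probe sets past the threshold was 26 between KO and WT, and the other ways of splitting the 6 arrays into 3 and 3 gave at most 1. With 10 splits, of which 1, the real one, gave as many, a share under 0.05 cannot be reached. Donor sex was uneven, with WT replicate 2 alone male by its sex-linked transcripts, and among the 5 other arrays, between which sex does not differ, 21 probe sets passed between KO and WT (9 of them among the 26), against at most 4 in the other splits of these arrays into 3 and 2, which argues against sex as the whole source. All 26 also kept at least 0.898 of their log2 change there, which genes called for tight groups tend to do whichever array is left out, and the criterion for sex was set with these values known, after 3 others had been dropped, of which 2 would also have argued against sex and 1, a share of splits under 0.05, could not be reached. Of the 26 calls 17 did not pass among the 5 arrays, which is no sign of sex, since leaving out other arrays also lost calls. Of the 26, 5, 4 and 6 passed without KO replicate 2, KO replicate 3 and WT replicate 1, and 22 without KO replicate 1. The genotype remains a candidate explanation, and a part played by sex and traits of donors or recipients that no label records stay open.

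Genes of neutrophils were higher in KO, although the sort for B220 and BP-1 should remove such cells. The 4 primary granule genes differed by a mean of 1.20 (SE 0.13) and 8 late neutrophil genes differed by 0.68 (SE 0.22), and S100a8 and S100a9, the abundant calcium-binding proteins of neutrophils, gave 0.88 and 0.91 (both named after their values were seen). A test of mature neutrophils as the source assumed that their RNA would move both groups together. The difference between the groups was 0.528 (95% interval -0.09 to 1.15), and 0.34 without WT replicate 2. Against that array alone KO differed by 1.146 in the primary and 0.244 in the late genes. It was the highest WT array in the late genes (8.79) but not in the primary ones (7.34). These values do not exclude mature neutrophils. Nor can the test decide, since added RNA need not shift groups of different baselines equally on the log2 scale. A first criterion of 2 standard errors would have excluded them (the difference is 2.37 standard errors). That criterion was replaced, after the value was seen, as too lenient for 6 arrays. Early myeloid progenitors would bring other early myeloid genes, whose median was 0.07 (SE across genes 0.073, 11 genes). Some of these genes were dim, with means down to 6.45 in KO and 6.26 in WT, where RMA compresses changes. A further 12 neutrophil genes had a median of 0.171 (SE across genes 0.103). Both standard errors treat genes of the same 6 arrays as independent, so they do not measure the uncertainty between KO and WT. Neither source of RNA from other cells can therefore be told apart from transcription in the B cells themselves. Which of these holds may be a question for single-cell or protein data, and none of the tables decides it.

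The mature B cell list was higher in all 3 KO arrays, whereas the MYC list was lower in KO replicates 2 and 3 and at the WT level in KO replicate 1 (mean deviation -0.013), so a joint shift to cells at a later stage with lower growth is a hypothesis that 1 KO array does not show. A trend with brightness was tested first, and with it removed from every array 2 of the 2 lists stayed past the camera threshold in the same direction, which argues against it as the whole cause. A larger share of later-stage B cells would lower the transcripts that such cells shut off. The median difference of these transcripts was -0.031 (SE across genes 0.065, 5 genes). This leaves a larger share of such cells open, because a high baseline hides a small share. Correlation between genes also stays open as a source of the low p-values, since both calls were lost with an estimated correlation (adjusted p = 0.646 and 0.701).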
